A study of Mus musculus with 7 samples.

How the data were processed

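RNA sequencing was done by the submitters on 7 libraries of mouse bone marrow-derived macrophages in 4 groups, set by each sample's title: WT M0 (n = 2), KO M0 (n = 1), WT LPS (n = 2) and KO LPS (n = 2). The authors deposited a table per library with TPM per gene, 23337 genes each, and every library sums to 1000000, so the TPM were scaled to a common total by the authors before deposit. The genome build was mm10, per the submitters' processing notes. The aligner, the quantification tool and the gene annotation are not given in the sources used here, nor is whether reads were counted by strand or how reads shared between gene copies were assigned, so values of near-identical copies, overlapping genes and short RNAs are uncertain.

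TPM keep no depth, so sequencing depth is unknown and no counting interval can be given. The spacing of low values relative to WT M0 replicate 2 was 0.847 in WT M0 replicate 1 and between 1.215 and 1.302 in the others, but that spacing was held by 5.52% to 7.74% of low genes, too few to recover reads. The tests planned before the data were examined assumed read counts. As the plan set out for normalized values, limma was used in their place, on log2(TPM + 1), because the tables hold TPM.

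Genes with a mean TPM of at least 1 over the 7 libraries were kept (11096). Group means were fitted over all 7 libraries with limma 3.58.1 in R 4.3.3, with variances moderated along a mean trend (3 residual degrees of freedom, prior 7.3) and Benjamini-Hochberg adjustment at 0.05. The comparisons were KO LPS vs WT LPS, KO M0 vs WT M0, WT LPS vs WT M0, KO LPS vs KO M0 and the interaction (the knockout LPS change minus the wild-type one), 5 in all. The lone KO M0 library is assumed to vary like the other groups. Gene names were matched to the RefSeq table of GRCm38.p6: 20756 by symbol, 2285 by synonym, 1 by gene number and 295 unmatched. Coordinates are from that table, whose assembly is the one mm10 is built on. Transcript length and GC content were taken from the longest GENCODE M21 transcript of a gene.

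The rule for named genes was fixed before the data were examined: Tgm2 first; per comparison the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, changed by at least 1 log2 unit, at a mean TPM of at least 5 in the higher group (planned for counts scaled to their total) and with libraries of the groups not overlapping (not asked for the interaction); 12 set genes always; and up to 4 members with the smallest p from each gene list. Predicted or unnamed gene models, pseudogenes and antigen receptor segments are not named, and some genes that the rule selects are not reported here. Members of the sex and strain list and Col1a1 given by TPM, and the genes used for tests in the closing section, may fall outside it and were chosen after their values were seen.

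In all 35 gene lists were fixed beforehand, of pathways, macrophage states, markers of other cell types, sex and strain genes and the neighbours of Tgm2. A total of 34 had a member in the tables and 29 had at least 5 tested genes. Tgm2 was left out of every list. Lists were tested with camera (limma) at a preset correlation of 0.01, which compares a list with all other genes, again with an estimated correlation, and with fry. With 3 residual degrees of freedom no list was called with an estimated correlation in any comparison. LPS-induced and LPS-repressed genes were defined from the LPS change averaged over the genotypes.

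The steps were tested on simulated data with the real spread and with 200 of 11096 genes changed, 5 times. The means were taken over all untreated or all LPS libraries, so without a genotype effect. For WT LPS vs WT M0 they were taken over all 7 libraries, so without an LPS effect either. For KO LPS vs WT LPS the test recovered 82.8% of changes of 1 log2 unit and 100% of changes of 2, with 7.86% false among calls. For WT LPS vs WT M0 it recovered 79.8% and 99.8%, with 6.59% false, and for KO M0 vs WT M0 55.8% and 99.2%, with 6.48% false. Camera called 20 of 20 shifted lists and 0 of 380 unshifted ones. The simulated noise was independent between genes and the lists were drawn at random. This does not show how often camera calls lists of correlated genes falsely at the preset correlation.

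Alternatives were median-ratio scaling, a pseudocount of 0.1, no filter, an adjusted p of 0.01, each library left out in turn, the compared groups alone, and the replicate number as a block. Quantile normalization, a minimum mean TPM of 5, autosomal genes alone and a fit without both WT LPS libraries were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.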

Results

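Gene expression was measured by RNA sequencing in bone marrow-derived macrophages, which are bone marrow cells grown into macrophages with the growth factor M-CSF, from wild-type mice and mice lacking Tgm2. Tgm2 encodes transglutaminase 2, an enzyme that crosslinks proteins. Cells had 7 days of M-CSF at 25 ng/ml and were then left untreated (M0) or given lipopolysaccharide (LPS), a bacterial cell wall component sensed by Tlr4, at 10 ng/ml for 6 hours. The 7 libraries formed 4 groups: wild type untreated (WT M0, n = 2), knockout untreated (KO M0, n = 1), wild type with LPS (WT LPS, n = 2) and knockout with LPS (KO LPS, n = 2). All are labelled male. Values were TPM, transcript levels scaled for gene length and to a common total, which keep no sequencing depth, so depth is unknown. The single KO M0 library has no replicate, and nothing in the labels says that replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 11096 genes.

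Tgm2 transcripts were lower in every knockout library than in every wild-type library. Tgm2 lies on chromosome 2 from 158116405 to 158146392 (GRCm38, protein-coding). Its TPM was 433 and 368 in WT M0, 50.7 in KO M0, 233 and 199 in WT LPS, and 19.4 and 19.2 in KO LPS. The knockout log2 fold change was -2.95 (SE 0.20, limma adjusted p 0.00029) in untreated cells and -3.41 (SE 0.16, adjusted p 4.5e-06) under LPS. LPS lowered Tgm2 in wild type (log2 fold change -0.89, adjusted p 0.0013) and in knockout cells (-1.35, adjusted p 0.0004). Gene-level TPM do not show which exons the remaining reads came from.

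Both WT LPS libraries differed from the other 5 in sex-linked transcripts. Xist, the X-inactivation RNA made in cells with more than a single X chromosome, stood at 47.2 and 55.4 TPM in WT LPS and at 0.00535 TPM or listed at 0 in each of the other 5. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower in WT LPS than in KO LPS, with ratios of mean TPM of 0.525, 0.515, 0.458 and 0.437. All 4 passed the limma test with all libraries, with adjusted p from 0.0049 to 0.042. Not all of them were followed through the alternatives: Uty, with the highest adjusted p, was not. Kdm5d missed the threshold with no filter on low values (adjusted p 0.112) and without WT LPS replicate 1 (0.112), KO LPS replicate 1 (0.0659) or KO LPS replicate 2 (0.133). Every comparison that uses WT LPS (KO LPS vs WT LPS, WT LPS vs WT M0 and the test of the difference between LPS responses) carries this difference. KO M0 vs WT M0 and KO LPS vs KO M0 do not compare those libraries, which enter them through the gene filter and the shared estimate of the spread.

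**Figure D1:**
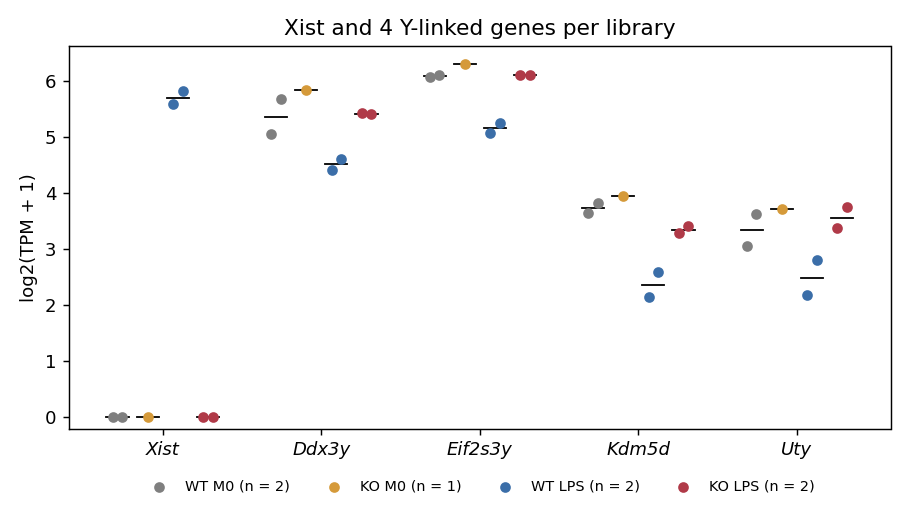
Xist and 4 Y-linked genes in log2(TPM + 1) on the vertical axis for each of the 7 libraries, coloured by group, with a line at each group's mean. Xist stood at 47.2 and 55.4 TPM in the 2 WT LPS libraries and at 0.00535 TPM or less in the others, and the Y-linked genes are lower in WT LPS than in KO LPS.

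In wild-type cells LPS raised inflammatory and interferon-stimulated genes and lowered others, including Clec10a and Mrc1. Lcn2, which binds bacterial iron carriers, rose by a log2 fold change of 7.86 (SE 0.17) and Nos2, the inducible nitric oxide synthase, by 7.69 (SE 0.22). Serpinb2 (7.89), Il6 (5.87), Ptgs2 (4.75) and Il1b (3.89) also rose. Il1b went from 257 ± 48.7 to 3812 ± 610 TPM (SD, n = 2). St6gal1 (-5.90), Hpgd, which degrades prostaglandins (-5.45), Clec10a, a lectin of alternative activation (-5.24), and Lmna (-4.99) fell. The mannose receptor Mrc1 fell by 3.17, while Ccl2 (0.56, SE 0.28, adjusted p 0.13) and Il10 (0.02, SE 0.23, adjusted p 0.95) did not pass the limma test, Ccl2 passing it without WT LPS replicate 2 (1.06, adjusted p 0.0055).

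Of the 60 tested interferon-stimulated genes, 58 rose and 1 fell in wild type (58 and 1 adjusted over the list alone). Among pro-inflammatory cytokines and mediators 23 of 26 rose and 1 fell (23 and 1 adjusted over the list alone), and among chemokines 13 of 23 rose and 4 fell (14 and 4). Of 24 cholesterol biosynthesis genes 20 rose and 1 fell (20 and 1 adjusted over the list alone), including Fdps (3.24, SE 0.17) and Fdft1 (3.43, SE 0.19), enzymes of the path from isoprenoids to squalene. Of 31 antioxidant (Nrf2) genes 16 rose and 5 fell (17 and 6 adjusted over the list alone), led by the cystine transporter Slc7a11 (4.76). Of 44 oxidative phosphorylation genes 22 fell and 0 rose (23 and 0 adjusted over the list alone). Relative to the median gene, whose log2 fold change was -0.21, list medians were 3.56 (interferon-stimulated), 3.40 (pro-inflammatory), 2.21 (cholesterol biosynthesis), 0.74 (antioxidant) and -0.28 (oxidative phosphorylation). With camera at a preset correlation these lists had adjusted p of 7.9e-44, 3.3e-18, 3.4e-14, 7.8e-06 and 0.027. With an estimated correlation the adjusted p was 0.326 for the first 4 and 0.678 for the last. The oxidative phosphorylation call was lost with median-ratio scaling (adjusted p 0.0994) and without WT M0 replicate 1 (0.169), WT LPS replicate 1 (0.0541) or WT LPS replicate 2 (0.0599).

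In all, 4949 genes passed in WT LPS vs WT M0, 1665 higher and 3284 lower. The split depends on the scaling: median-ratio scaling of the TPM, which moved the median gene by 0.20, gave 2416 higher and 2348 lower, and quantile normalization, chosen after seeing the data, gave 2251 and 2539.

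Knockout cells responded to LPS with many of the same changes. Lcn2 (log2 fold change 9.64, SE 0.21), Nos2 (8.97, SE 0.27), Il6 (8.55, SE 0.33) and Il12b (6.31, SE 0.27) rose, as did Ccl2 (4.27, SE 0.34). Zdhhc14 (-6.13), St6gal1 (-5.82), Hpgd (-5.17) and the scavenger protein Cd5l (-4.77) fell. Interferon-stimulated genes rose in 58 of 60 cases with 0 falling, and pro-inflammatory genes in 24 of 26 with 0 falling, each with the same counts adjusted over the list alone. Of 39 cell cycle genes 24 rose and 2 fell (24 and 4 adjusted over the list alone), among them the mitotic cyclins Ccnb1 (3.37, SE 0.32) and Ccnb2 (3.25, SE 0.29). Of 24 cholesterol biosynthesis genes 5 rose and 3 fell (5 and 3 adjusted over the list alone). List medians relative to the median gene (-0.24) were 3.77, 4.22, 1.72 and 0.41, with camera adjusted p of 1.4e-46, 7.6e-24, 1.1e-08 and 0.037. With an estimated correlation the adjusted p was 0.256, 0.256, 0.342 and 0.669, and the cholesterol biosynthesis call was lost without KO LPS replicate 1 (0.0524). Of 24 cholesterol efflux and nuclear receptor genes 17 fell and 1 rose (18 and 1 adjusted over the list alone), and of 20 alternative activation markers 14 fell and 2 rose (15 and 2). Camera adjusted p was 0.00034 and 0.0020, and 0.256 for each with an estimated correlation.

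The knockout comparison called 4233 genes, 1533 higher and 2700 lower, or 2104 and 1854 with median-ratio scaling, which moved the median gene by 0.23, and 1837 and 2153 with quantile normalization. It rests on a single untreated library, assumed to vary like the other groups. Left out of the fit, the WT LPS libraries changed it little, to 4143 calls, an alternative chosen after seeing the data. Across 11095 genes other than Tgm2, which are not independent replicates, the LPS fold changes of the genotypes correlated with Pearson's r of 0.88 and Spearman's rho of 0.82. These comparisons share no library. Both called 1175 genes higher and 2158 lower, against 230 and 799 for independent lists, and 27 genes in opposite directions.

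Without LPS, Tgm2 was the 1 gene that passed the limma test between genotypes. Tnf (-0.07, SE 0.28), Il1b (0.27, SE 0.22), Nos2 (0.32, SE 0.27), Ccl2 (-0.56, SE 0.34), Arg1 (0.22, SE 0.29) and Tlr4 (0.35, SE 0.31) did not pass. At an unadjusted p under 0.05 there were 154 genes, against 555 expected by chance. No list held a member that passed, also when adjusted over the list alone. By camera 6 lists were called, with medians of -0.41 (stromal, endothelial and osteoblast markers), 0.26 (cell cycle), -0.10 (oxidative phosphorylation), -0.09 (chemokines), -0.09 (extracellular matrix) and -0.08 (antioxidant). Their adjusted p was 0.921 with an estimated correlation, and without WT M0 replicate 1 the oxidative phosphorylation, chemokine and antioxidant calls were lost (0.830, 0.434 and 0.522), the latter pair also with quantile normalization (0.189 and 0.191), as was the cell cycle call without WT M0 replicate 2 (0.272). Interferon-stimulated genes passed without WT M0 replicate 1 (3.6e-05) and antigen presentation without WT M0 replicate 2 (0.0346). WT M0 replicate 1 stood apart: WT M0 replicate 2 was closer to KO M0 (median absolute log2 difference 0.0959) than to WT M0 replicate 1 (0.221). Across genes, the fold changes of this comparison followed transcript length (Spearman's rho 0.33) and GC content (-0.40). Without replicate 2 the comparison called 6 genes, and with the untreated libraries alone 40. The self-test recovered 55.8% of simulated changes of 1 log2 unit and 99.2% of those of 2 here, so changes of about 1 unit could be missed.

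Under LPS the knockout libraries held more transcript of inflammatory cytokines and chemokines than the wild-type libraries. Il6, a cytokine of the acute phase, stood at 667 ± 71.3 TPM in KO LPS and 104 ± 47.1 in WT LPS (SD, n = 2), a log2 fold change of 2.74 (SE 0.27, limma adjusted p 0.00021). Il12b, a subunit of interleukins that drive T cell responses, stood at 90.1 ± 6.85 against 9.48 ± 2.54 TPM (3.14, SE 0.22). The monocyte attractants Ccl7 (4.19, SE 0.36), Ccl2 (3.15, SE 0.28) and Ccl12 (3.07, SE 0.52) and the synthases Nos2 (1.60, SE 0.22) and Ptgs2 (1.49, SE 0.24) were higher. Tnf (1.06, SE 0.23, adjusted p 0.018) and Cxcl10 (1.97, SE 0.42, adjusted p 0.019) were higher too, with adjusted p over the alternatives from 0.0025 to 0.177 and from 0.00071 to 0.211. Tnf missed the threshold with median-ratio scaling (0.0653), no filter on low values (0.159), and without WT LPS replicate 2 (0.177) or KO LPS replicate 1 (0.0966). Cxcl10 missed it with median-ratio scaling (0.0646), no filter (0.211), and without either WT M0 library (0.0552, 0.0516), WT LPS replicate 2 (0.0512) or KO LPS replicate 2 (0.122). With no filter Ccl12 (0.140), Nos2 (0.0621) and Ptgs2 missed it too. Il1b (0.14, SE 0.18), Il10 (0.81, SE 0.23, adjusted p 0.059) and Tlr4 (-0.36, SE 0.25) did not pass, though Il10 passed without WT LPS replicate 1 (1.11, adjusted p 0.028). Mrc1 (0.74, SE 0.22, adjusted p 0.078) did not pass with all libraries and passed without either WT M0 library (0.0342, 0.0337) and with the libraries of the compared groups alone (0.0351).

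Of 26 pro-inflammatory genes 13 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.90. Of 23 chemokines 10 rose and 3 fell (12 and 4 adjusted over the list alone), with a median of 0.90; Pf4 fell (-1.34, SE 0.16). Camera adjusted p was 1.4e-11 and 0.0038, and 0.297 and 0.375 with an estimated correlation. NF-kappaB components (2 of 32 rose, 4 adjusted over the list alone, median 0.22) and interferon-stimulated genes (2 of 60 rose, 1 adjusted over the list alone, median 0.30) had camera adjusted p of 0.0043 and 1.7e-05, or 0.487 and 0.720 with an estimated correlation. Both calls were lost without WT LPS replicate 2 (adjusted p 0.398 and 0.964).

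**Figure D2:**
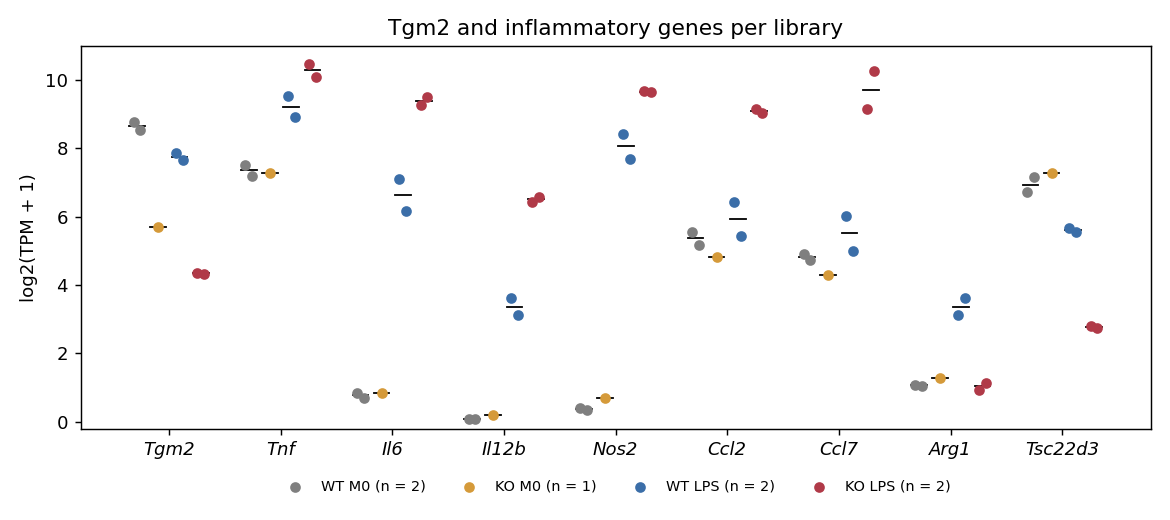
Tgm2 and 8 other genes as log2(TPM + 1) on the vertical axis, a point per library and a line at each group's mean. Il6, Il12b, Ccl2 and Ccl7 are higher in both KO LPS libraries than in both WT LPS libraries, and Arg1 and Tsc22d3 are lower.

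Cell cycle genes rose and cholesterol biosynthesis genes fell in KO LPS relative to WT LPS. Of 39 cell cycle genes 31 rose and 0 fell (34 and 0 adjusted over the list alone), with a median of 1.98. They include Ccnb2 (3.04, SE 0.23), the ubiquitin-conjugating enzyme Ube2c (3.03, SE 0.29), Ccnb1 (2.92, SE 0.26) and the centromere histone Cenpa (2.53, SE 0.18). Ccnb2 stood at 56.4 ± 4.59 TPM in KO LPS, 5.99 ± 0.702 in WT LPS and 4.88 ± 1.81 in WT M0. Of 24 cholesterol biosynthesis genes 0 rose and 20 fell (0 and 22 adjusted over the list alone), with a median of -1.73. Sqle, squalene epoxidase, fell by 2.24 (SE 0.19), Cyp51 by 2.17 (SE 0.18) and Hmgcs1 by 2.04 (SE 0.18). Hmgcs1 stood at 29.0 ± 4.18 TPM in WT M0, 197 ± 30.9 in WT LPS and 46.7 ± 1.58 in KO LPS. The camera adjusted p was 9.4e-33 and 7.5e-32, and 0.205 for each with an estimated correlation. The WT LPS libraries in this comparison are those with Xist at 47.2 and 55.4 TPM.

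**Figure D3:**
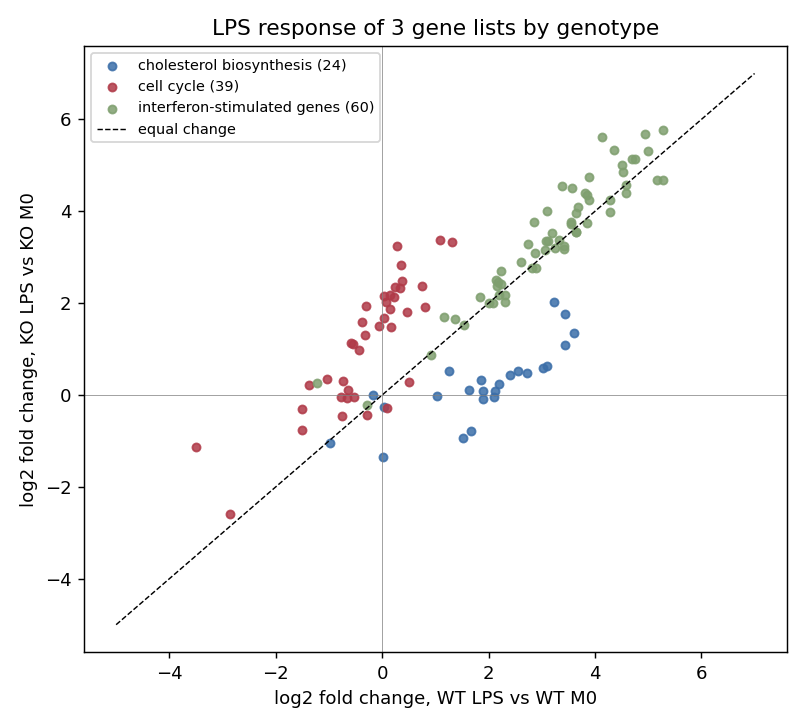
LPS response of 3 gene lists, with the log2 fold change in wild type on the horizontal axis and in knockout on the vertical axis, a point per gene and a dashed line where they are equal. Cholesterol biosynthesis genes lie mostly below the line, with list medians of 2.00 in wild type and 0.17 in knockout, and cell cycle genes mostly above it, with medians of -0.05 (0.09 with median-ratio scaling) and 1.48.

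Genes of alternative activation, lipid handling and antioxidant defence were among those lower in KO LPS. Arg1, arginase 1, fell by 2.32 (SE 0.24), to 1.07 ± 0.219 TPM against 9.45 ± 2.50 in WT LPS and 1.10 ± 0.0215 in WT M0. Mmp12 (-1.58, SE 0.19) and Itgax (-1.25, SE 0.20) also fell. With no filter on low values Itgax missed the threshold (adjusted p 0.0543). Of 20 alternative activation markers 0 rose and 5 fell (3 and 7 adjusted over the list alone, median -0.25). Of 24 cholesterol efflux and nuclear receptor genes 1 rose and 5 fell (1 and 8, median -0.37), including Scd2 (-3.42, SE 0.33), a fatty acid desaturase. Of 31 antioxidant genes 0 rose and 9 fell (0 and 13, median -0.40), including Gclc (-1.39, SE 0.15), which makes glutathione, and Nqo1 (-1.10, SE 0.18). Camera adjusted p was 0.0043, 5.2e-07 and 1.8e-08, and 0.297, 0.205 and 0.205 with an estimated correlation. The glucocorticoid-responsive gene Tsc22d3 fell by 2.82 (SE 0.19) and the TGF-beta family member Gdf3 by 2.79 (SE 0.19). The MHC class II genes H2-Aa (-1.12), Cd74 (-1.16) and H2-Eb1 (-1.04) fell, Cd74 missing the threshold with no filter (adjusted p 0.0658), while their list, antigen presentation and costimulation, did not pass (camera adjusted p 0.663).

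The genes with the largest falls included transcripts that were high in WT LPS and low or listed at 0 elsewhere. Ifi208, listed under its older name Pydc3, stood at 61.0 and 35.2 TPM in WT LPS and at 1.56 TPM or less in the other 5. Ptgfr, the prostaglandin F receptor, stood at 19.4 and 10.4 TPM in WT LPS and is listed at 0 in the other 5. Erdr1 fell by 3.17 (SE 0.29). Mir5130 had a log2 fold change of 5.14 (SE 0.60) with KO LPS values as far apart as 96.9 and 15.9 TPM, and as a microRNA, a short RNA, its TPM are uncertain. It missed the threshold with no filter on low values (adjusted p 0.0665).

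KO LPS vs WT LPS called 795 genes, 509 higher and 286 lower, of which 341 and 147 changed by at least 1 log2 unit, and 2215 genes had an unadjusted p under 0.05 against 555 expected. Quantile normalization gave 390 higher and 335 lower. The count was 385 without KO LPS replicate 2, 428 without WT LPS replicate 2 and 506 without KO LPS replicate 1, and 307 with no filter on low values. Of 951 genes induced by LPS on average over the genotypes, 76.9% were higher in KO LPS, with 176 rising and 56 falling (camera p 4.5e-11, and p = 0.068 with an estimated correlation). Of 1528 repressed genes, 48.2% were higher, against 53.1% of 4848 genes not called for LPS, with 62 rising and 82 falling (camera p 0.063 downward, and p = 0.607 with an estimated correlation). Camera passed for them without WT M0 replicate 1 (p 0.0368) and without KO LPS replicate 1 (p 0.000501).

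**Figure D4:**
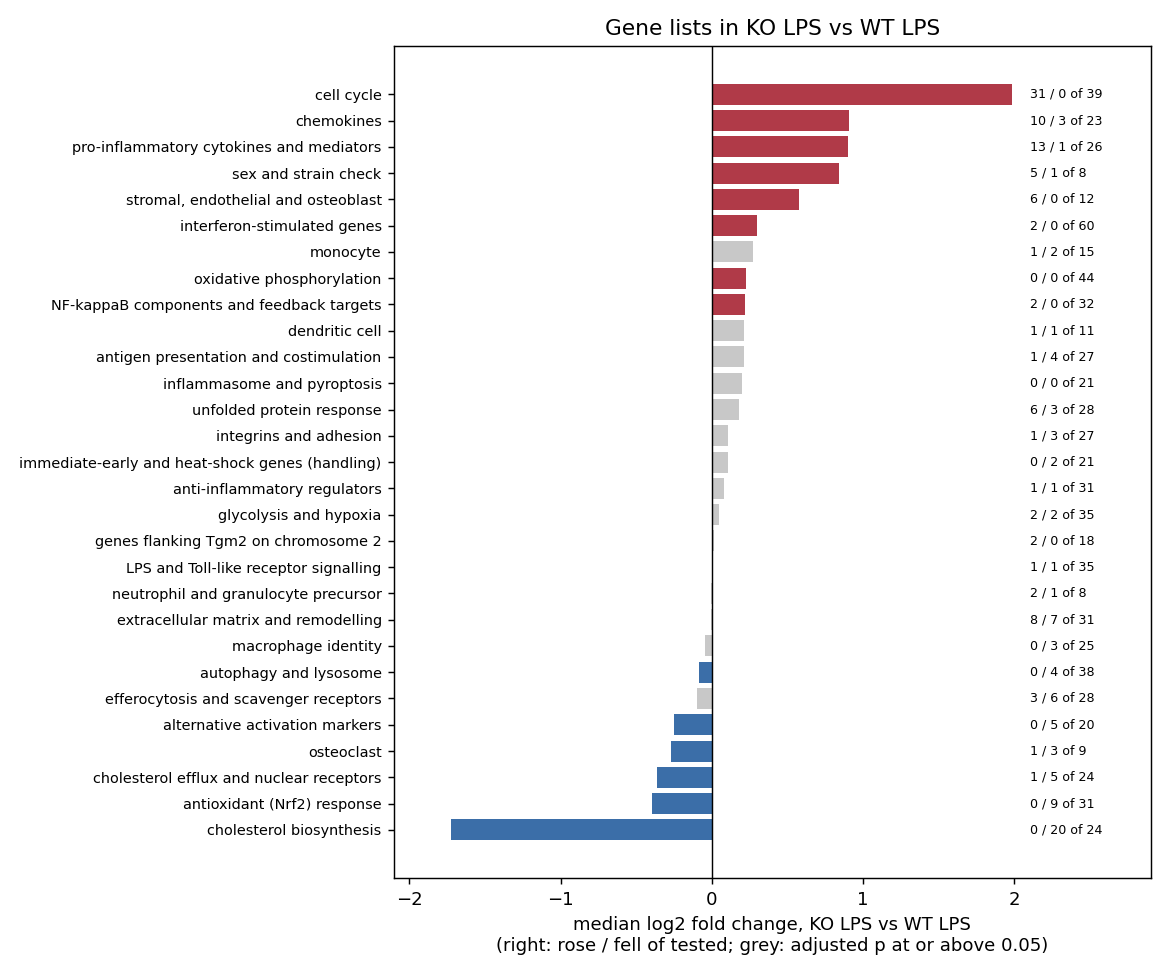
Median log2 fold change in KO LPS vs WT LPS, on the horizontal axis, of the 29 gene lists with at least 5 tested members, coloured where the camera adjusted p at a preset correlation was under 0.05. Cell cycle (1.98) and cholesterol biosynthesis (-1.73) lie at the ends; none of the lists passed with an estimated correlation.

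The remaining lists differed little or in mixed directions between KO LPS and WT LPS. Of 38 autophagy and lysosome genes 0 rose and 4 fell, led by the proton pump subunit Atp6v0d2 (-2.03, SE 0.20). Their camera adjusted p was 0.033, or 0.618 with an estimated correlation, and the call was lost with quantile normalization (adjusted p 0.110) and without WT LPS replicate 1 (0.0510), KO LPS replicate 1 (0.0528) or KO LPS replicate 2 (0.0505). No oxidative phosphorylation gene passed of 44 (median 0.22, camera adjusted p 0.010, or 0.656 with an estimated correlation), and without WT LPS replicate 1 the list's adjusted p was 0.0510. Extracellular matrix genes went both ways, 8 rising and 7 falling of 31, with Mmp2 (1.42, SE 0.21) higher and Ctsl (-0.97, SE 0.15) lower. Efferocytosis and scavenger receptors had 3 rising and 6 falling of 28, with Marco (2.21; adjusted p 0.123 with no filter) and Gas6 (1.64) higher and Cd36 (-1.18) and Havcr2 (-1.61) lower. The unfolded protein response had 6 rising and 3 falling of 28. Fewer than 3 members passed in each direction for Toll-like receptor signalling, anti-inflammatory regulators, and glycolysis and hypoxia, and 0 of 21 inflammasome genes passed. Integrins and adhesion had 1 rising and 3 falling of 27, immediate-early and heat-shock genes 0 and 2 of 21, and macrophage identity genes 0 and 3 of 25 (camera adjusted p 0.978, 0.818 and 0.057). Macrophage identity passed downward without WT LPS replicate 2 (adjusted p 0.0221) or KO LPS replicate 1 (0.0487), and without WT LPS replicate 2 so did the immediate-early and heat-shock list (0.0410) and efferocytosis and scavenger receptors (0.0221). Of 18 genes flanking Tgm2 on chromosome 2, 2 rose, including Fam83d (1.85). The calls in the sex and strain list include the sex-linked difference given above. Ddx3y, Eif2s3y, Kdm5d and Uty were higher in KO LPS and Xist was lower (-5.70). The sex and strain list had 5 rising and 1 falling of 8 (median 0.84, mean -0.03, camera adjusted p 0.029 upward, or 0.487 with an estimated correlation), a call lost without WT LPS replicate 1 (0.0510) or KO LPS replicate 2 (0.116). Of other transglutaminases, F13a1 (-0.74) and Tgm4 (-0.54) were tested and did not pass over all genes, while 0 rose and 2 fell adjusted over the list alone. F13a1 passed with the libraries of the compared groups alone (adjusted p 0.0311) and without WT M0 replicate 1 (0.0304) or 2 (0.0305).

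Markers of other cell types were low or moved with LPS. Only 2 T and NK cell genes, 2 B cell genes and 3 erythroid genes reached the expression filter. S100a8, a neutrophil and monocyte gene that macrophages also express, stood at 7.31 ± 0.0301 TPM in WT M0, 259 ± 88.2 in WT LPS and 124 ± 38.7 in KO LPS. Stromal markers had 6 rising and 0 falling of 12 in KO LPS vs WT LPS (median 0.57, camera adjusted p 0.010, or 0.375 with an estimated correlation), a call lost without KO LPS replicate 2 (0.0929). Among them Col1a1 stood at 13.2 and 18.6 TPM in WT M0, 10.4 in KO M0, 1.18 and 1.56 in KO LPS, and is listed at 0 in both WT LPS libraries. Neutrophil, dendritic cell and monocyte markers had 2 rising and 1 falling of 8, 1 and 1 of 11, and 1 and 2 of 15 (camera adjusted p 0.978, 0.663 and 0.978). Osteoclast markers had 1 rising and 3 falling of 9 (camera adjusted p 0.010, or 0.297 with an estimated correlation, and 0.0510 without WT LPS replicate 1).

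The difference between the LPS responses of the genotypes was tested directly as an interaction, which uses the WT LPS libraries with Xist. It passed for 152 genes, 94 with a more positive and 58 with a more negative change in knockout cells. Ccl7 (4.70, SE 0.58), Ccl2 (3.71, SE 0.44), Il12b (3.02, SE 0.35) and Il6 (2.68, SE 0.43) had the more positive change, as did Ccnb2 (2.97, SE 0.37) and the replication factor Mcm10 (2.93, SE 0.34). Gdf3 (-3.61, SE 0.31), Scd2 (-3.48, SE 0.52), Tsc22d3 (-3.17, SE 0.30), the chemokine receptor Cxcr4 (-2.69, SE 0.48) and Arg1 (-2.54, SE 0.37) had the more negative change. Tnf (1.13, adjusted p 0.22), Nos2 (1.28, adjusted p 0.15), Ptgs2 (1.39, adjusted p 0.15) and Tgm2 (-0.46, adjusted p 0.60) did not pass, though Nos2 passed without WT LPS replicate 1 (adjusted p 0.0403). With no filter on low values each gene named here as passing missed the threshold, with adjusted p from 0.0501 (Gdf3) to 0.253 (Cxcr4). Without WT M0 replicate 1, Ccl7, Ccl2, Il6, Scd2, Cxcr4 and Arg1 missed it (adjusted p 0.0617 to 0.143). Il6 also missed it with median-ratio scaling (0.0551) and without WT M0 replicate 2 (0.0548) or KO LPS replicate 2 (0.0540), and Cxcr4 without KO LPS replicate 1 (0.0581) or 2 (0.0516) and with quantile normalization (0.0507). Of 24 cholesterol biosynthesis genes 15 had a more negative change (21 adjusted over the list alone, median -1.95), and of 39 cell cycle genes 16 had a more positive change (30 adjusted over the list alone, median 1.62), with camera adjusted p of 3.6e-31 and 1.5e-31, or 0.253 for each with an estimated correlation. The count was 16 without WT M0 replicate 1, 93 without WT M0 replicate 2, 72 without KO LPS replicate 1, 64 without KO LPS replicate 2, 92 with a pseudocount of 0.1 and 10 with no filter on low values. The split turned to 7 more positive and 9 more negative without WT M0 replicate 1, to 1 and 9 with no filter and to 13 and 15 at an adjusted p under 0.01. Genotype fold changes with and without LPS, which share no library, were uncorrelated across 11095 genes (Pearson's r -0.00095, Spearman's rho -0.0041). With a library of a replicated group left out in turn, Pearson's r ran from -0.092 to 0.084. The untreated fold changes rest on the single KO M0 library and followed transcript length and GC content. The lack of correlation therefore does not show that a knockout difference needs LPS.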

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

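Tests of the sex-linked genes, of the uniformly stronger response and of the origin of the WT LPS cells were chosen after the results they bear on were seen; those of chromosome share, transcript length and GC content were set before, and the rules for reading the tests of Xist under LPS (more than once, including which comparison decides it and what it was taken to show) and of the repressed genes (the spread over left-out libraries was added) were changed after their values had been seen.

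The interaction test, of the knockout LPS change minus the wild-type one, passed for 152 genes. It uses the WT LPS libraries with Xist. A genotype difference in the LPS response therefore cannot be told apart from another origin of those cells. The log2 difference was 5.14 for Mir5130, 4.70 for Ccl7, 3.71 for Ccl2, 3.05 for Fam177a2, 3.02 for Il12b, 2.97 for Ccnb2, 2.93 for Mcm10, 2.78 for Marco, 2.68 for Knstrn and 2.68 for Il6. It was -6.55 for Ifi208, -5.70 for Xist, -4.36 for Erdr1, -3.93 for Ptgfr, -3.61 for Gdf3, -3.48 for Scd2, -3.17 for Tsc22d3, -2.69 for Cxcr4, -2.55 for Mid1 and -2.54 for Arg1. The values of Xist and Ptgfr, listed at 0 in most libraries, depend on the pseudocount and are no bounds. The lone KO M0 library could not be left out of the interaction. Of these 20 genes, 8 passed in each fit that left out 1 library, and without WT M0 replicate 1 all 12 others missed the threshold. With no filter on low values 19 of the 20 missed it, Xist excepted, among them 7 of those 8 (adjusted p 0.0513 for Ifi208 and 0.116 for Erdr1 and Ccnb2). Mir5130, Fam177a2 and Marco missed it with median-ratio scaling (0.0755, 0.120 and 0.133) and quantile normalization (0.0636, 0.136 and 0.113), Fam177a2 and Marco with a pseudocount of 0.1 (0.0594 and 0.0777), Il6 with median-ratio scaling (0.0551) and Cxcr4 with quantile normalization (0.0507). These 5 also missed it without libraries other than WT M0 replicate 1: 2 genes without WT M0 replicate 2, 1 and 3 without WT LPS replicates 1 and 2, and 3 each without KO LPS replicates 1 and 2.

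By camera at a preset correlation, the interaction was also called for 12 lists, with the same limit. Median differences were 1.62 (cell cycle), 1.11 (pro-inflammatory), 1.05 (chemokines), 1.04 (stromal, endothelial and osteoblast), 0.30 (oxidative phosphorylation), 0.26 (interferon-stimulated) and 0.21 (NF-kappaB). They were -1.95 (cholesterol biosynthesis), -0.44 (osteoclast), -0.38 (cholesterol efflux and nuclear receptors), -0.37 (antioxidant) and -0.19 (alternative activation). None passed with an estimated correlation, where adjusted p ran from 0.253 (cell cycle and cholesterol biosynthesis among them) to 0.868 (interferon-stimulated). At the preset correlation, alternative activation missed the threshold with median-ratio scaling (adjusted p 0.0573) and without KO LPS replicate 1 (0.0841) or WT M0 replicate 2 (0.0981), and osteoclast without WT LPS replicate 1 (0.0666) or WT M0 replicate 2 (0.0888). NF-kappaB missed it without WT LPS replicate 2 (0.168), and interferon-stimulated genes without WT M0 replicate 1 (0.102), KO LPS replicate 2 (0.179) or WT LPS replicate 2 (0.397, with camera's direction turned). Lists gaining a call were antigen presentation without WT LPS replicate 1 (0.0305), efferocytosis without WT LPS replicate 2 (0.0446) and macrophage identity without WT M0 replicate 1 (0.0469).

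Xist was present in both WT LPS libraries and nearly absent from the other 5, although all are labelled male. Both KO LPS libraries, with the same LPS, list Xist at 0 (KO LPS vs WT LPS log2 fold change -5.70, limma adjusted p 8.1e-07). This argues against LPS switching on Xist in XY cells of both genotypes, but not in wild type alone. Xist switched on by LPS in XY cells would also leave the Y-linked LPS change alike in the genotypes to within 0.3. The median interaction of 4 Y-linked genes, 0.71, lies beyond that bound. Their mean, 0.65, has a 95% interval from -0.41 to 1.71 that spans it, so a switch in wild type alone stays open. The mean log2 level of these 4 genes in WT LPS was lower than in WT M0 (-0.996, -1.67 to -0.32) and than in KO LPS (-0.97, -1.65 to -0.30). That does not decide, since with LPS it was also lower in knockout cells (-0.35, -1.17 to 0.48). Without LPS it was higher in knockout than wild type (0.32, -0.50 to 1.15), and neither of these changes went beyond its spread. XX cells among the WT LPS cells are a candidate explanation. The 4 Y-linked genes were lower in both WT LPS libraries than in both KO LPS libraries, with a median log2 difference of -0.96. With as much Y-linked RNA per XY cell in each group, the XX share would be 58.9% and 45.0% in WT LPS replicates 1 and 2. Xist had the opposite order, at 47.2 and 55.4 TPM. No bound was set for the X-linked partners of the Y-linked genes. Kdm5c and Ddx3x had WT LPS to KO LPS ratios of 0.974 and 0.987 and Kdm6a and Eif2s3x of 1.33 each. None of the 4 passed (limma adjusted p 0.235 to 0.980). In WT LPS vs WT M0, Eif2s3x passed (log2 fold change 0.60, limma adjusted p 0.018), while Kdm6a (-0.24), Ddx3x (-0.35) and Kdm5c (0.07) did not. In KO LPS vs KO M0 the change of Eif2s3x was -0.07.

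The 795 genes that differed under LPS may reflect several things. A uniformly stronger LPS response in the knockout would raise induced genes, and 76.9% of them were higher (65.3%, camera p 0.035, for genes induced in wild type alone, which are chosen with the WT LPS libraries), but it would also move cholesterol biosynthesis genes, which LPS raised in wild type, further up, and their median was -1.73 (a list fixed beforehand but taken for this test after its fall was seen; with the wild-type response from a single WT LPS library and KO LPS set against the other, so that none is shared, the medians were 1.84 and -1.94, or 2.27 and -1.55). The rise of that list in wild type comes from the 2 WT LPS libraries that held Xist, and its median in KO LPS vs KO M0 was 0.17. The cholesterol values therefore speak against a uniformly stronger response only if LPS, not the origin of those cells, caused the rise. For repressed genes, which a uniformly stronger response would lower, the test does not decide. Of them 51.4% were lower, against 46.9% of genes not called for LPS (camera p 0.063, downward). The share was 42.8% without WT LPS replicate 2 and 56.7% without KO LPS replicate 1. Genes on X and Y made up 3.52% of the calls (24 on X and 4 on Y) against 3.15% of tested genes, so most calls lie elsewhere. WT LPS cells from other animals or another culture than the other 5 libraries cannot be told apart from the genotype. The reason is that both of the 2 WT LPS libraries held Xist. Nnt, of the sex and strain list, stood at 6.61 and 7.72 TPM in WT LPS. In the other 5 libraries it stood between 12.4 and 23.9 TPM. It passed in WT LPS vs WT M0 (log2 fold change -1.28, limma adjusted p 0.0014) and not in KO LPS vs WT LPS (0.093). A sex difference acting through autosomal genes and a difference in strain were not tested and stay open, as does the genotype itself.

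WT M0 replicate 1 stood apart from the other untreated libraries. Its log2 difference from them followed transcript length (Spearman's rho across genes -0.45, against -0.0012 for KO M0 minus WT M0 replicate 2) and GC content (0.40, against -0.19), over 10970 genes, 98.9% of those tested. A library preparation or RNA quality difference is therefore a candidate source, and length and GC cannot be separated here by these values. For the fold changes of the comparisons that use WT M0, rho was 0.33 for length and -0.40 for GC in KO M0 vs WT M0, 0.10 and -0.29 in WT LPS vs WT M0 and -0.09 and 0.20 in the interaction, against 0.05 and -0.17 in KO LPS vs KO M0 and 0.08 and 0.01 in KO LPS vs WT LPS, which do not compare WT M0. No biological explanation was tested.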

How the results depend on the processing

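Quantile normalization, the mean TPM minimum of 5, autosomal genes alone and the fit without both WT LPS libraries were chosen after seeing the data. Limits are 2 or fewer libraries per group, TPM without depth, 3 residual degrees of freedom and Xist at 47.2 and 55.4 TPM in the WT LPS libraries. The tests that need counts (limma-voom, other count models, the 50-count filter) were not run; library totals alone are the TPM as deposited. KO LPS vs WT LPS called 795 genes, 362 at an adjusted p under 0.01, 307 with no filter, 770 on autosomes and between 385 and 804 with 1 library left out (428 without WT LPS replicate 2, 506 and 385 without KO LPS replicates 1 and 2). KO M0 vs WT M0 called 1, then 2 with a pseudocount of 0.1, 20 with no filter, 40 with the untreated libraries alone and 1 to 6 with a library left out (6 without WT M0 replicate 2). KO LPS vs KO M0 called 2681 at an adjusted p under 0.01. The lone KO M0 library could not be left out of the comparisons that use it, so their dependence on it was not tested. The interaction called 152, then 28 at an adjusted p under 0.01, 92 with a pseudocount of 0.1, 10 with no filter (1 shared with the 152) and 16 to 139 with a library left out (16 and 93 without WT M0 replicates 1 and 2, 72 and 64 without KO LPS replicates 1 and 2). A stricter threshold lowers counts by construction; for the other changes the cause was not tested. Lists called numbered 14 in KO LPS vs WT LPS, 0 with an estimated correlation, 11 by directional fry and 25 in either direction, and 12 for the interaction, 0 with an estimated correlation, 1 by directional fry and 21 in either direction. The call of the induced genes in KO LPS (76.9% higher, a share the correlation does not enter) was lost with an estimated correlation (camera p 0.068). So was each list call in every comparison. Relative to the other genes camera's direction turned for oxidative phosphorylation in KO M0 vs WT M0 without WT M0 replicate 1 (median -0.0078, adjusted p 0.830; down to -0.20 without WT M0 replicate 2) and for interferon-stimulated genes in the interaction without WT LPS replicate 2 (median 0.0055, adjusted p 0.397; up to 0.44 without WT LPS replicate 1); the cause was not tested. The labels do not say that replicate numbers mark a shared animal or day, and with 2 numbers the correlations of same-numbered libraries' deviations (0.08, 0.30 and 0.18) do not settle it, so libraries were not treated as paired; with the replicate number as a block KO LPS vs WT LPS called 1115, including Mrc1 (0.74, adjusted p 0.0408), and WT LPS vs WT M0 5632, including Ccl2 (0.56, adjusted p 0.046). The 20 genes named by size in KO LPS vs WT LPS, in WT LPS vs WT M0 and in KO LPS vs KO M0 passed in each fit that left out 1 library.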

Other observations

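The tests of the splits and of the glucocorticoid genes were set before their results were seen.

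Of 8 neutrophil markers 7 rose and 1 fell with LPS in each genotype (camera adjusted p 7.1e-06 in wild type and 1.1e-05 in knockout, or 0.326 and 0.256 with an estimated correlation), and of 15 monocyte markers 8 rose in each while 6 fell in wild type and 4 in knockout. Ly6c2, a monocyte surface antigen, stood at 273 and 241 TPM in WT LPS and at 66.3 and 90.4 in KO LPS, against 1.13 or less without LPS, and fell by 1.72 (SE 0.31) in KO LPS relative to WT LPS, a call lost with a pseudocount of 0.1 (adjusted p 0.303), no filter on low values (0.134) and without KO LPS replicate 1 (0.0536). Wfdc21 is listed at 0 in the untreated libraries and stood at 15.2 and 19.5 TPM in WT LPS and 29.2 and 46.7 in KO LPS. The dendritic cell gene Fscn1 was higher in KO LPS than WT LPS (2.11, SE 0.19), as was the endothelial receptor Kdr (1.89, SE 0.24), and the immediate-early gene Fos was lower (-1.34, SE 0.20), though with no filter on low values it missed the threshold (adjusted p 0.0582).

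Called as a single factor over both genotypes, LPS against no LPS gave 5920 genes. Of the 35 splits of the 7 libraries into 4 and 3, only the real 1 gave as many, the highest other calling 1. Each other split mixes LPS and untreated libraries, so the LPS difference itself widens its spread and lowers its count. With 35 splits, and replicates not shown to be separate animals or cultures, chance is not excluded by this test.

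Tsc22d3, which glucocorticoids induce, fell in KO LPS relative to WT LPS, and lower glucocorticoid receptor activity is a candidate explanation. Of 7 other target genes fixed for this, 5 were tested: their median was -0.11, 4 of 5 were lower, and Sgk1 (-1.15, SE 0.16) and Klf9 (-1.05, SE 0.21) passed while Fkbp5 (0.50, SE 0.22), Per1 (-0.11) and Ddit4 (-0.00057) did not. With members going both ways the test does not decide.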
